A study of Drosophila melanogaster with 2 samples.

How the data were processed

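Whole embryos aged 4 to 20 h of a Drosophila melanogaster line expressing Abd-B with a C-terminal GFP were used for ChIP-seq with an antibody against GFP, in 2 biological replicates of 1 group, per the labels. Chromatin was sonicated to 200 to 800 bp, per the labels. The deposited data used here were peak lists on genome build dm6, per the labels: 1 list per replicate, 1 pooled list and 1 list that passed the authors' optimal IDR threshold. Each replicate list was made by the authors from that replicate's alignment and a control file, and the IDR list from the replicate and pooled lists, per the deposited text descriptions. The aligner, its version and the peak caller are not given in the sources used here.

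The authors' lists give each peak's position, summit, a signal value and the −log10 of a q-value. The deposited signal value is an enrichment measure whose scale is not given in the sources used here, so it was used only to rank peaks within a list. The authors' −log10 q-value reached 3.82 in the IDR list, where the lowest was 2.025. At q of 0.05 or less the lists held 4333 peaks for replicate 1, 8557 for replicate 2 and 6677 for the pooled list. Each replicate list and the pooled list hold 30000 peaks, so a low rank does not mean enrichment. They hold no read counts: the depth is unknown, intervals cover the counting of peaks or genes only, and differences in depth between the replicates were not corrected. Control, untagged and signal track values were not used here. Coordinates are 1-based.

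Peaks were sorted by signal value, then q-value, then position. The reference was the RefSeq sequence and the Ensembl release 115 annotation (BDGP 6.54), on the 6 main arms 2L, 2R, 3L, 3R, 4 and X, and all peaks on these arms fitted inside the arm lengths of that assembly. The 1 replicate 2 peak and 1 pooled peak outside these arms were left out. The genes comprised 13945 protein-coding genes. Gene symbols of the fixed lists were matched directly or through a unique synonym, and 1 symbol, ambiguous between 2 genes, was left out of the posterior spiracle list. A summit near the TSSs of several genes counted for each of them.

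Replicates were compared by summits within 100 bp among the 5033 strongest peaks of each list, with 100 circular shifts along each arm for the chance level. Feature classes were assigned to the summit base in the order promoter (500 bp of a TSS), 5' UTR, coding sequence, 3' UTR, other exon, intron and intergenic, and tested against the share of bases with an exact binomial test. For 22 gene complexes, the summits between the first and last base of the member genes were compared with 10000 permuted positions of the interval (one-sided). For 31 gene lists the share of genes with a summit within 1 kb of any TSS was compared with other protein-coding genes by Fisher's exact test. Motifs on either strand within 100 bp of the summit were compared with flanks 400 to 500 bp away on both sides by an exact McNemar test, beside up to 50 other orders of the same bases. The rank trend was tested by 100000 permutations, and 1 motif ratio has a bootstrap interval from 10000 resamples of peaks. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and intervals of shares are 95% Wilson intervals.

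The tests, lists, complexes, motifs and main alternatives were fixed before the data were examined. The explanations weighed in the closing section were set out only after feature shares, GC content by rank, motif shares and list counts had been seen, though before the values that decide them were computed, except for the test of a second copy of Abd-B. Named genes were Ubx, abd-A and Abd-B, the genes nearest to the 20 strongest peaks, and members of the lists with the highest ranked promoter summit. A list that passed gave 4 such members and the first 2 in alphabetical order without a summit, and another list gave up to 2. The alternatives were stricter peak lists, each replicate alone, other windows and distances, random lists matched on deciles of gene territory and on 3 classes of TSS number, and other complex intervals. Matching on GC content in 200 bp windows, a background of genes with any pooled peak, and other base orders for the rank and distance tests were added after seeing the data.

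The functions were tested on simulated data with fixed seeds. Over 20 draws of random gene hits among 13945 genes, the list test made 1 call and the matched test 0. For 5033 simulated peaks, 59.6% of summits were made to match and 59.9% were found. With an AT-rich centre alone, 46 of 50 other orders were as high as TTTATKG, and with the motif planted in 15.3% of centres none was. Bases were drawn independently there, unlike genomic sequence. The simulation thus does not show that a smaller excess of the motif would be found in these data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.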

Results

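Genome-wide binding of a tagged Abd-B protein was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 4 to 20 h. Abd-B is the most posterior Hox transcription factor of the fly and specifies the posterior abdominal segments. The embryos came from a transgenic line that carries Abd-B fused to GFP at its C-terminus, and an antibody against GFP was used for the precipitation. There was 1 group of 2 biological replicates and no second group, so the design implies a comparison of the replicates with each other and a description of where the protein was found. Each replicate list held 30000 peaks, with a median width of 384 bp in replicate 1 and 380 bp in replicate 2. The list that passed the authors' irreproducible discovery rate (IDR) threshold held 5033 peaks with a median width of 390 bp. Those 5033 were the peaks with the highest signal values in the pooled list, and their signal values, on the authors' own scale, ran from 152.7 to 5202. Read depth is unknown, because the peak lists give no read counts. All p-values over peaks or genes describe this peak list, since peaks and genes are not independent replicates.

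The first question was how far the replicates placed their strongest peaks at the same positions. Both ranked the same 3 sites highest: the promoter of CG14100 on 3L, an intron of ush on 2L, and the promoter of mRpL41, which encodes a mitochondrial ribosomal protein, on 2R. Among the 5033 strongest peaks of replicate 1, 3528 (70.1%, 95% Wilson interval 68.8 to 71.35%) had a replicate 2 summit within 100 bp. Circular shifts of the replicate 2 summits gave a mean of 0.739% and a highest value of 1.03% over 100 shifts. The IDR list was made from these same replicates, so the shares and the rank correlation of its peaks are set in part by that selection. Of the IDR peaks, 79.1% had a summit among the 5033 strongest peaks of replicate 1 and 89.2% among those of replicate 2. With the IDR list divided into 4 parts by strength, the share found among the 5033 strongest of both replicates was 98.2%, 91.5%, 68.7% and 22.1% (19.9 to 24.5%), where the weakest part lies next to the rank limit. In the full replicate lists 92.1% of IDR peaks (91.3 to 92.8%) had a summit in both, from 98.3% in the strongest part to 85.7% (83.7 to 87.5%) in the weakest. The share of replicate 1 peaks with a partner depended on the distance allowed, from 58.2% within 50 bp to 76.1% within 250 bp. Across the 4634 IDR peaks found in both full replicate lists, the ranks had a Spearman rho of 0.753, which is a correlation across peaks.

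Abd-B-GFP summits lay mainly at promoters and in introns and hardly ever in coding sequence outside promoters. Within 500 bp of an annotated transcription start site (TSS) lay 2444 of the 5033 IDR summits (48.6%, 47.2 to 49.9%), 3.58 times the 13.6% of bases in this class. Every other class covers only bases farther than 500 bp from any TSS, and summits in coding sequence or UTRs nearer to one count as promoter. So counted, coding sequence makes up 13.7% of the bases and held 5 summits (0.0993%, 0.0424 to 0.232%), a ratio of 0.00724. This ratio was 0.00434 without replicate 1, 0.0159 without replicate 2 and 0.0227 against bases of the same GC content, of which 4.37% were coding. Introns held 34.5% of summits against 39.5% of bases (exact adjusted p = 4.39e-13), and intergenic DNA held 15.1% against 27.2% (adjusted p = 7.28e-94). The 3' UTRs held 0.636% against 4.43% (exact adjusted p = 8.35e-59) and the 5' UTRs 0.417% against 0.779% (adjusted p = 0.00257). Other exons, at 0.755% against 0.820%, did not pass the test (exact adjusted p = 0.6955). These are exact binomial tests, two-sided, with Benjamini-Hochberg adjustment over the classes, and the promoter p rounded to 0 at computer precision. The 5' UTR difference did not pass in the 1000 strongest peaks (exact adjusted p = 0.119) or against bases of the same GC content (adjusted p = 0.117).

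**Figure D1:**
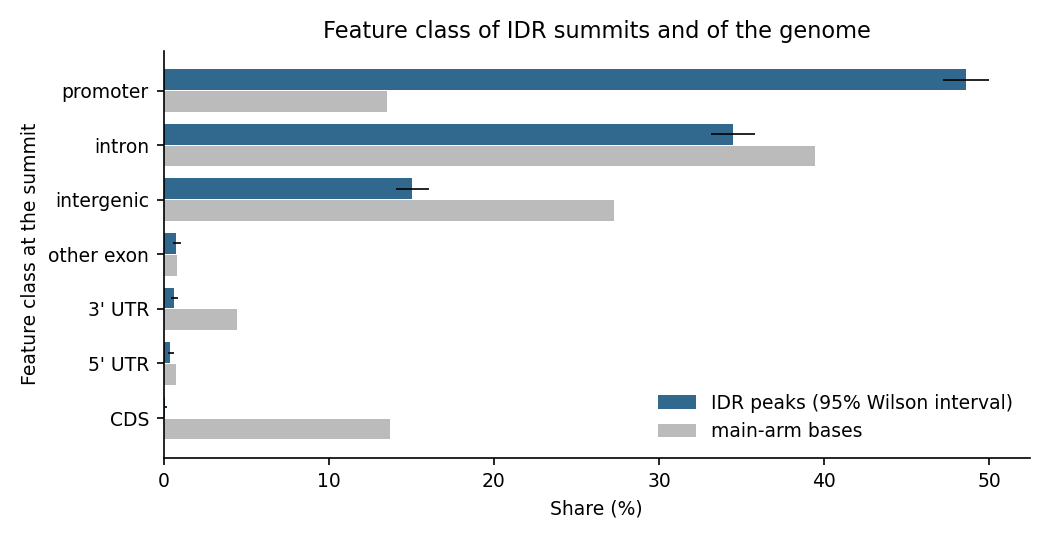
Share of the 5033 IDR summits (blue bars, with 95% Wilson intervals) and of main-arm bases (grey bars) in each feature class, in percent. Promoters, within 500 bp of a TSS, held 48.6% of summits and 13.6% of bases, while coding sequence (CDS) outside promoters held 0.0993% and 13.7%.

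Within 1 kb of a TSS lay 2943 summits (58.5%, 57.1 to 59.8%), 2.48 times the 23.6% of bases so placed. At protein-coding genes, 2254 of the 2749 summits within 1 kb of the nearest TSS (82.0%, 80.5 to 83.4%) were upstream of it. Their median position was 121 bp upstream, with quartiles at 236 and 42 bp upstream. The promoter share within 500 bp declined along the pooled list, from 63.6% in the 1000 strongest peaks to 52.2% at ranks 1001 to 2500 and 40.5% at ranks 2501 to 5033. The summits were rich in A and T: GC content over 200 bp averaged 34.9% (SD 7.26 over summits), against 43.7% in flanks 400 to 500 bp away and 42.15% over the main chromosome arms. It was 33.0% in the 1000 strongest peaks.

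Of the 20 strongest peaks, 14 lay in promoters, 5 in introns and 1 between genes, and each had a partner in both replicates, at rank 34 or better in replicate 1 and rank 28 or better in replicate 2. The strongest, at 3L 19590433 to 19590816 (dm6) with a signal value of 5202, had its summit 96 bp upstream of CG14100. The next, at 2L 480900 to 481286 (signal value 3752), lay in an intron of ush, a cofactor of GATA factors, 1400 bp upstream of cbt, which encodes a zinc finger protein. The third, at 2R 15217569 to 15217935 (signal value 3524), lay 146 bp upstream of mRpL41. Chro, a chromodomain protein, had a summit 101 bp downstream of its TSS, and ph-p, a subunit of Polycomb repressive complex 1, had one 486 bp upstream of a TSS. Trl, which encodes GAGA factor, had a summit in an intron 1535 bp downstream of a TSS, and chinmo, a BTB zinc finger gene, was the nearest gene to an intergenic summit 12473 bp upstream. The HmgZ summit lay 566 bp upstream of its nearest TSS, inside an intron. The other genes nearest to these summits were Ugalt, Tcs5, CG4004, px, PNPase, CG5611, Art3, CG32772, CG11050, Pdrg1, Atat and cu. For CG4004 the nearest TSS was 5057 bp away, and that summit lay at a promoter of the long noncoding RNA Vinr.

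The bithorax complex, which holds Ubx, abd-A and Abd-B, was the gene complex with the most summits. From 16656623 to 16972236 on 3R it held 42 IDR summits, 13.3 per 100 kb against 3.76 per 100 kb over the main arms. The short sloppy-paired complex was denser, at 14.8 per 100 kb from 2 summits (87.9 percentile of permuted positions). The Abd-B gene itself (16927212 to 16972236) held 15, of which the strongest, rank 496, lay in an intron at 16958176, and the next, rank 520, lay 48 bp upstream of an Abd-B TSS at 16960329. Between abd-A and Abd-B lay 14 summits, including the strongest of the complex, rank 301 at 16871506, in an intron of MSAmiP and of the long noncoding RNA iab8. Between Ubx and abd-A lay 10, of which 7 were in the noncoding bxd transcript, with the strongest at 16764229 (rank 414). The Ubx gene (16656623 to 16734426) held 2 and the abd-A gene (16807214 to 16830049) held 1, and neither had a summit within 1 kb of a TSS. Of the 42, 40 had a partner in both full replicate lists. When the interval's position was permuted 10000 times, 99.7% of positions held fewer summits (permutation p = 0.0028, one-sided), but over 22 complexes this did not pass (adjusted p = 0.0616). It passed with permuted positions centred on genes (permutation adjusted p = 0.0176) or with 10 kb added on either side (adjusted p = 0.0396).

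**Figure D2:**
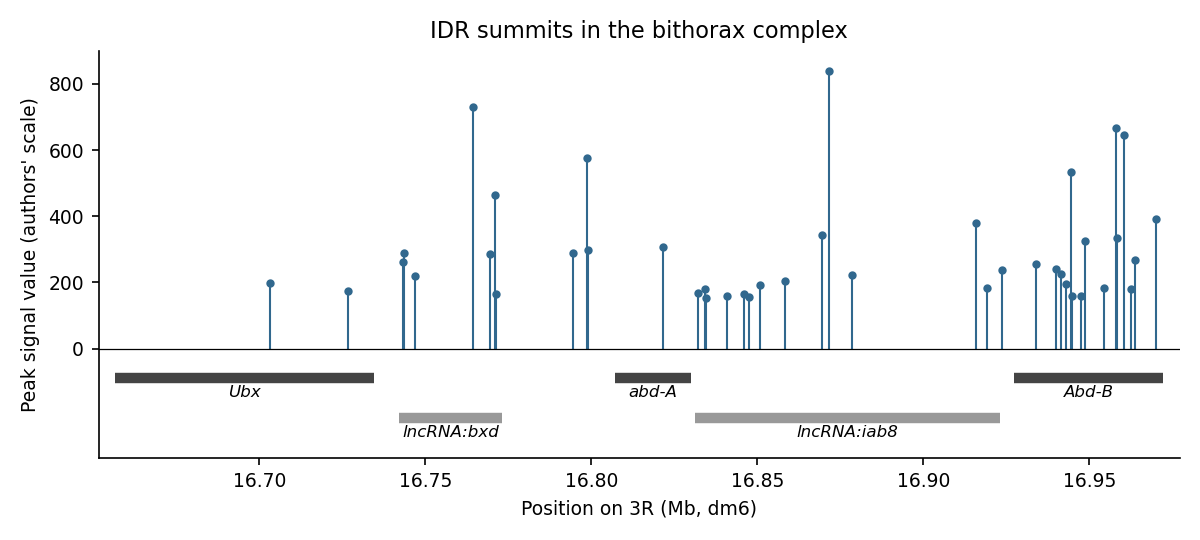
Map of the bithorax complex on 3R (horizontal axis, Mb, dm6), with each of the 42 IDR summits drawn as a line whose height is the authors' signal value. Bars under the axis show 3 protein-coding genes (dark) and 2 long noncoding RNAs (light), and the Abd-B gene held 15 summits against 2 in Ubx and 1 in abd-A.

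None of the other 21 complexes passed (smallest permutation adjusted p = 0.725). The Antennapedia complex held 18 summits in 337802 bp, at the 73.3 percentile of permuted positions. The reaper complex of cell death genes held 17 (82.4 percentile), the Wnt complex 7 (71.2 percentile), the odd-skipped genes 6 (86.8 percentile) and the Polycomb repressor pair Psc and Su(z)2 held 5 (91.4 percentile). No summit lay in the spalt, gooseberry, nubbin-pdm2, achaete-scute, Lcp65 cuticle or yolk and chorion control intervals. The intervals stop at the outer ends of their genes, so promoter summits just beyond them were not counted. A salm summit (rank 2312) lay 602 bp upstream of its TSS, outside the spalt interval. A nub summit (rank 1937) lay 614 bp upstream, outside the nubbin-pdm2 interval. Here salm is named outside the rule for named genes.

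Promoter summits were frequent at genes of the translation machinery. Of 13945 protein-coding genes, 3484 (24.98%) had an IDR summit within 1 kb of a TSS. Of 92 cytoplasmic ribosomal protein genes 48 had one (52.2%, 42.1 to 62.1%, exact adjusted p = 5.78e-07), with the strongest at RpL34b (rank 287), RpS27 (rank 337), RpL41 (rank 481) and RpS20 (rank 564), and none at RpL10 or RpL10Aa. The RpL41 summit had no partner in the replicate 2 list. Of 73 mitochondrial ribosomal protein genes 34 had one (46.6%, 35.6 to 57.9%, exact adjusted p = 0.00103), among them mRpL41 (rank 3), mRpS10 (rank 13), mRpS23 (rank 29) and mRpL23 (rank 31), while mRpL10 and mRpL12 had none. Random lists matched on gene territory and number of TSSs averaged 28.7% and 21.9% for these lists (permutation adjusted p = 0.00207 for each, the smallest they could give here). Among the 1000 strongest peaks neither list passed (exact adjusted p = 1 and 0.0517).

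Polycomb, trithorax and insulator genes and the EGFR pathway passed the test too, but in fewer settings. Of 22 Polycomb, trithorax and insulator genes 12 had one (54.5%, 34.7 to 73.1%, exact adjusted p = 0.0351). These included ph-p (rank 6), brm, the ATPase of the Brahma remodelling complex (rank 47), the insulator gene Cp190 (rank 64) and E(z), the histone H3 lysine methyltransferase of Polycomb repressive complex 2 (rank 98), but not Pc or Psc. In the EGFR pathway 8 of 12 genes had one (66.7%, 39.1 to 86.2%, exact adjusted p = 0.0351). The ligand genes spi (rank 160) and Krn (rank 370), the repressor aop (rank 1728) and the inhibitor aos (rank 2160) led this list, while Egfr itself and Star (S) had none. Both calls were lost without replicate 2 (exact adjusted p = 0.147 for the Polycomb list and 0.0502 for EGFR), with a 500 bp window (0.0515 and 1), at the most upstream TSS (0.0846 and 0.115) and with a 5 kb window (0.0832 and 0.332). They were also lost among genes with any pooled peak (exact adjusted p = 0.191 and 0.590) and against random lists matched on GC content near the TSS (permutation adjusted p = 0.0508 for each), as was the Polycomb call against lists matched on gene territory (permutation adjusted p = 0.141).

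Genes of adult chemoreception were nearly free of promoter summits. Only 3 of 179 odorant, gustatory and ionotropic receptor genes had one (1.68%, 0.572 to 4.81%, exact adjusted p = 7.29e-17): Or88a (rank 1452), Ir60b (rank 4164) and Gr32a (rank 4373). Gr10a and Gr10b were among those without. The share was 17.3% (31 of 179) with a 5 kb window and 7.82% over the gene body with 2 kb. Among genes with any pooled peak it was 6.67% (3 of 45), and the list passed as lower in each of these settings. All list tests are Fisher's exact tests, doubled one-sided, with Benjamini-Hochberg adjustment over 31 lists.

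The other 26 lists did not pass the test at adjusted p 0.05. Hox genes had promoter summits in 2 of 8 cases, Abd-B (rank 520) and Scr (rank 3631), of which the Scr summit had no partner in the replicate 2 list. Posterior spiracle genes, which include known Abd-B targets, had them in 6 of 14 (exact adjusted p = 0.591), led by crb (rank 1259) and shg (rank 2243). Hindgut regulators stood at 5 of 11, with bowl (rank 790) and Dr (rank 1752), and somatic gonad genes at 3 of 8, with dsx (rank 2482) and Sox100B (rank 2878). Glia genes had summits in 5 of 8 (62.5%, exact adjusted p = 0.211), with moody (rank 637) and loco (rank 3599). Pair-rule genes had them in 0 of 9 (upper limit 29.9%), testis genes in 0 of 14 (upper limit 21.5%, exact adjusted p = 0.184) and yolk and chorion genes in 0 of 13 (upper limit 22.8%, adjusted p = 0.211). Summits were present at 4 of 12 segment polarity genes, with nkd (rank 1501) and mid (rank 2340), and at 2 of 10 Wnt pathway genes, again nkd with Wnt6 (rank 3204). The BMP pathway had 2 of 13, brk (rank 222) and Mad (rank 463), and the FGF pathway 2 of 6, stumps (rank 1072) and htl (rank 1284). The Notch pathway had 3 of 10, with E(spl)m3-HLH (rank 351) and E(spl)m7-HLH (rank 1587), and the JAK-STAT pathway 2 of 8, Socs36E (rank 464) and Stat92E (rank 723).

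Among cell type and process lists, cell death genes had summits at 2 of 8, hid (rank 719) and Diap1 (rank 1279), and gap genes at 2 of 10, oc (rank 2017) and btd (rank 4940). Neural fate regulators had 4 of 18, with Dr and nub (rank 1937), and differentiated neuron genes 2 of 14, elav (rank 214) and Csp (rank 4321). Muscle regulators had 1 of 14, tin (rank 1158), and muscle structural genes 3 of 12, with sls (rank 540) and Tm1 (rank 1769). For Hox cofactors the count was 1 of 6, hth (rank 3017), and for tracheal genes 1 of 7, trh (rank 1709). Hemocyte and fat body genes had 3 of 10, with Hml (rank 1694) and ush (rank 1945), cuticle genes 1 of 12, rtv (rank 3796), and pigmentation genes 1 of 7, Ddc (rank 4355). Proteasome genes had 12 of 48, led by Rpn5 (rank 746) and Rpn3 (rank 1165).

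**Figure D3:**
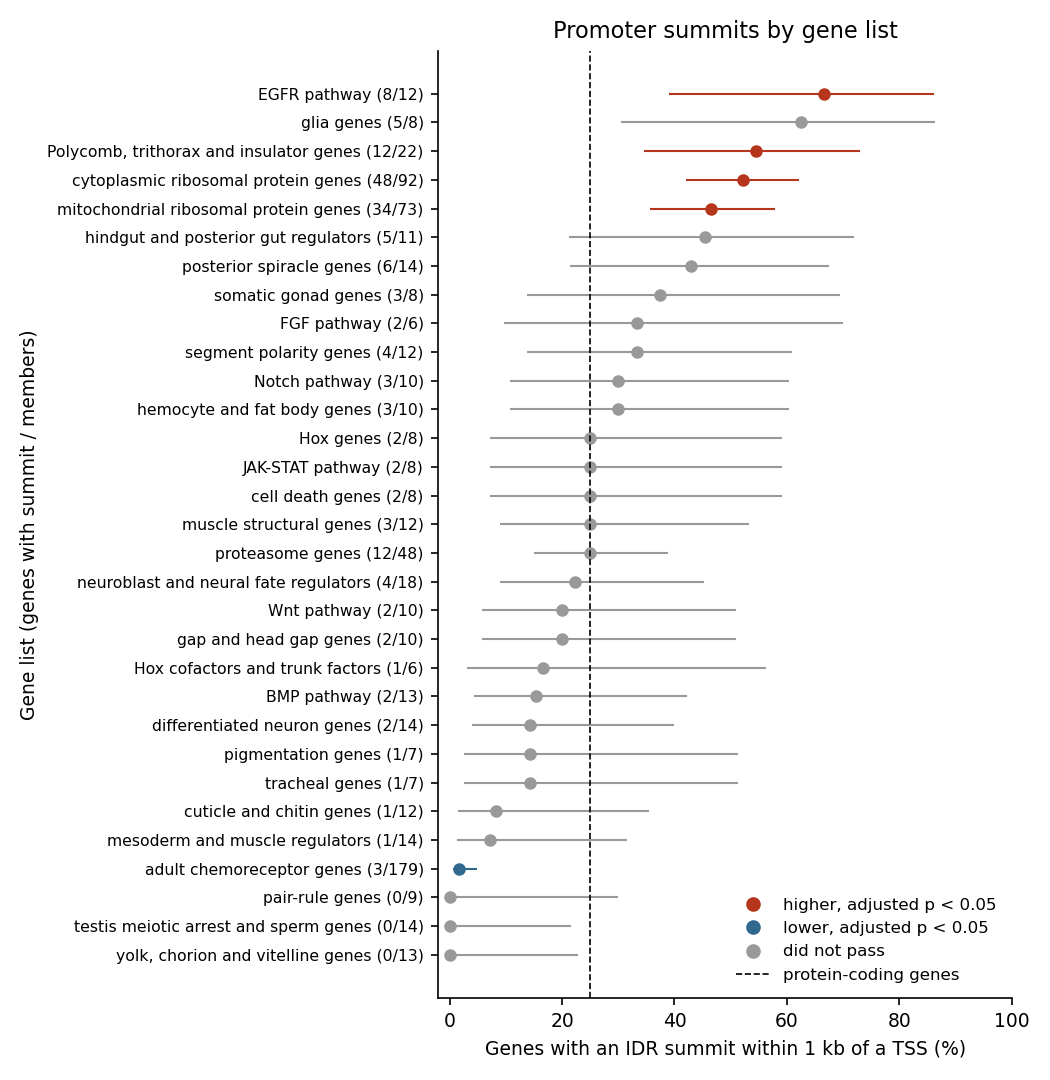
Percent of each list's genes with an IDR summit within 1 kb of a TSS (points, with 95% Wilson intervals), with the count and list size beside each name. The dashed line marks the 24.98% of all protein-coding genes, and 4 lists lay above it and 1 below at adjusted p under 0.05.

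The Abd-B motif TTTATKG (K is G or T) was present within 100 bp of 983 summits (19.5%, 18.5 to 20.7%) and in the flanks of 620 (12.3%, 11.4 to 13.3%), a ratio of 1.59 (exact adjusted p = 2.78e-23). Its 50 other base orders had a median ratio of 1.48 and a highest ratio of 1.88, and 16 of them were as high as the motif. The Hox core TAATTA had a ratio of 1.75 (exact adjusted p = 1.27e-30), and 11 of its 13 other orders were as high. The Caudal motif TTTATG, which lies inside the TTTATGG form of TTTATKG, had a ratio of 1.46 (exact adjusted p = 5.98e-26), with 17 of 29 orders as high. Of the joint Hox and Exd sites, TGATTTAT had a ratio of 1.36 (exact adjusted p = 0.0209) and TGATTAAT 1.34 (adjusted p = 0.1055), and 49 of 50 orders were as high for each.

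The DREF motif TATCGATA lay at 213 summits (4.23%) and in the flanks of 25 (0.497%), a ratio of 8.52 (exact adjusted p = 2.32e-37), and none of 50 orders was as high. Its ratio was 4 in the 1000 strongest peaks and 5.63 in the 2516 strongest. Motif 1, GGTCACAC, bound by M1BP, had a ratio of 4.86 (exact adjusted p = 5.27e-18), also with 0 of 50 orders as high. The BEAF-32 motif CGATA had a ratio of 1.36 (exact adjusted p = 1.33e-19), with 5 of 50 orders as high. CGATA lies inside TATCGATA, so every DREF site also counted as a BEAF-32 site. The GAGA factor motif GAGAG was less frequent at summits than beside them (20.6% against 25.8%, ratio 0.798, exact adjusted p = 4.52e-10), as was the Zelda motif CAGGTA (ratio 0.822, adjusted p = 0.0495). The other orders of GAGAG had a median ratio of 0.675, and 7 of 9 were as low as the motif. Those of CAGGTA had a median of 0.816, with 24 of 50 as high. Within 200 bp of the summit the GAGA ratio turned to 1.02 (exact adjusted p = 0.4625). These are exact McNemar tests, two-sided, adjusted over 10 motifs. TGATTTAT did not pass without replicate 2 (exact adjusted p = 0.176), and among the 2516 strongest peaks neither it (0.194) nor CAGGTA (0.2415) did. In the 1000 strongest peaks TGATTTAT passed, with a ratio of 2.64 (exact adjusted p = 0.00728). No other base orders are given for that subset, whose summits averaged 33.0% GC, so base composition is not excluded there. Over all IDR peaks 49 of 50 orders were as high as TGATTTAT.

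**Figure D4:**
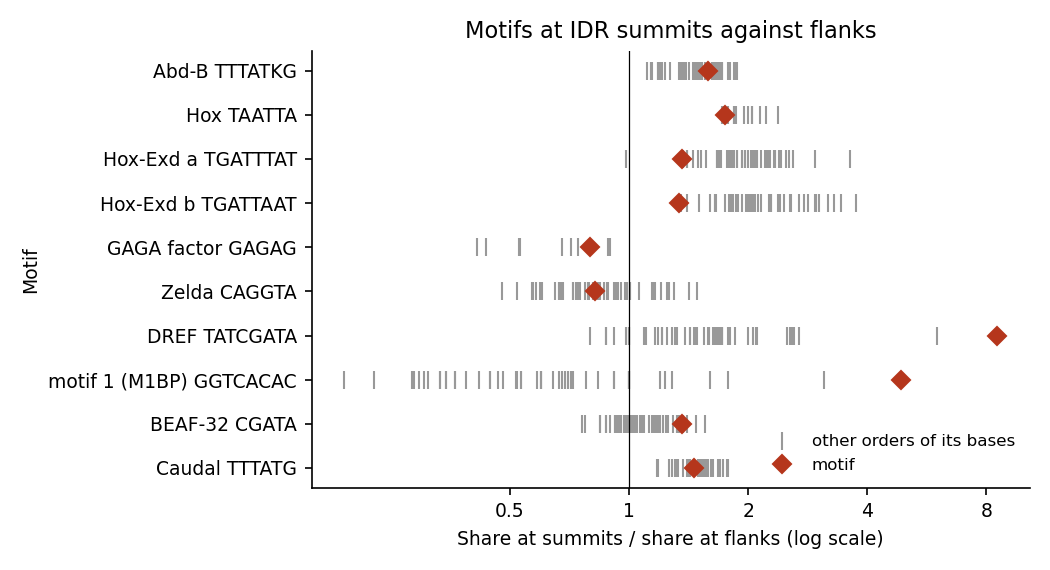
Ratio of the share of peaks with a motif within 100 bp of the summit to the share with it in the flanks (horizontal log axis), for 10 motifs (red diamonds) and for other orders of each motif's bases (grey ticks; the 1 order with a ratio of 0 is not drawn). DREF at 8.52 and motif 1 at 4.86 exceeded all of their other orders, while TTTATKG at 1.59 lay inside the range of its own.

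The strongest peaks did not carry TTTATKG more often than the weaker ones. Over 4 parts of the list by strength, it was present in 19.3% (17.2 to 21.6%) of the strongest, 18.0% and 18.6% of the middle parts and 22.2% (20.0 to 24.6%) of the weakest. Spearman's rho between strength and the motif was -0.0293 (permutation p = 0.0374, two-sided, 100000 resamples), and no longer passed without replicate 1 (p = 0.670) or replicate 2 (p = 0.0862). Its sign turned in the 2516 strongest peaks (rho 0.0107) and with the motif sought within 50 bp (rho 0.00297). Of 2090 summits farther than 1 kb from a TSS, 442 had the motif (21.1%, 19.45 to 22.95%), against 541 of 2943 promoter summits (18.4%, 17.0 to 19.8%). The odds ratio was 1.19 (Fisher's exact test, two-sided, p = 0.0156), and without replicate 1 it was 1.13 (p = 0.1025). It was 1.40 without replicate 2 (Fisher's exact test, p = 2.04e-06) and 1.22 with promoters taken within 500 bp (p = 0.00551). It turned to 0.908 in the 1000 strongest peaks (Fisher's exact test, p = 0.649) and was 1.08 in the 2516 strongest (p = 0.482). The flanks differed in the same direction, with the motif beside 15.45% of distal and 10.1% of promoter summits. Relative to flanks the order was therefore the other way, with a ratio of 1.37 at distal and 1.82 at promoter summits. Of the other base orders, 18 of 50 were as high at distal and 10 of 50 at promoter summits. The difference between these ratios was not tested.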

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

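The tests of a second copy of Abd-B and of ribosomal protein summits, the tests that match GC content or AT content and all tests on the weaker pooled peaks were chosen after the results had been seen. Of 4967 pooled peaks at ranks 5034 to 10000, 27.0% (25.7 to 28.2%) lay in promoters against 13.6% of bases, which is what drew attention to them. TTTATKG was present at 22.55% of these summits and in the flanks of 14.35%, a ratio of 1.57 (exact McNemar test, two-sided, p = 3.22e-27). None of the 50 other base orders used at IDR summits had a ratio as high here (highest 1.53), nor did any in a second draw of 50 (highest 1.53). Whether this differs from the IDR summits was not tested. In these peaks 69.8% had a summit in both full replicate lists, against a mean of 1.74% and a highest value of 2.215% over 100 circular shifts, but the pooled list was made from the same replicates.

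TTTATKG was more frequent at IDR summits than beside them, and base composition could account for this, since 16 of 50 other orders of its bases had a ratio as high. Against genome sites matched on GC content and promoter class the ratio was 1.16, below the 95th percentile of the other orders (1.19). Those orders had a median of 1.01 there, and 4 of 50 were as high as the motif. Bias in the sequencing or fragmentation of AT-rich DNA between precipitated and control libraries cannot be told apart from binding here, because 0 of the columns analysed held reads or a level per library before control normalization. No biological explanation was tested, as the design has 1 group.

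Promoters of cytoplasmic and mitochondrial ribosomal protein genes carried summits more often than other promoters. In random lists matched on the lowest GC content near a TSS both lists passed, at a permutation adjusted p of 0.00207, the smallest these could give. Those random lists averaged 24.96% for cytoplasmic and 25.03% for mitochondrial genes, against 24.98% of all protein-coding genes. Matching on this measure thus hardly moved the expected share, so the test could not decide whether AT-rich DNA near their start sites contributes. That these peaks mark active promoters without an Abd-B site stays open: at the 88 summits of these genes TTTATKG lay at 12 and in the flanks of 9, a ratio of 1.33 with a wide interval (95% bootstrap 0.545 to 3.67), and 34 of 50 other orders were as high. The ratio lay below the 95th percentile of those orders (3.33) and the interval's upper bound below their highest (4). This met the outcome set for peaks without an Abd-B site. With 88 summits and so wide an interval, Abd-B sites at some of them are not excluded. Over all promoter peaks the ratio was 1.82, below the 95th percentile of the other orders (2.00), with 10 of 50 as high. That is the outcome set for peaks without an Abd-B site, but it covers mostly other genes and decides nothing here. No expression values or untagged control were used here, and no biological explanation was tested.

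The bithorax complex held 42 summits, a density that did not pass over 22 complexes. A higher AT content is argued against as the cause, since 26.1% of its windows were AT-rich against 26.14% over the main arms. Matching on this share therefore moved the expected number little, from 12.1 to 13.3, and 0.690% of 10000 matched positions held as many (permutation adjusted p over 22 complexes = 0.154). A contribution of a second copy of Abd-B and its surroundings in the transgenic line was not excluded. The 13 summits from Ubx to abd-A stood at the 88.2 percentile of equally long random intervals, below the 95 set for that test. The DNA between Ubx and abd-A alone, however, held 13.7 summits per 100 kb, against 13.3 in the whole complex. How much sequence such a copy would carry is not given in the sources used here, so the test cannot decide. No biological explanation was tested.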

How the results depend on the processing

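The GC matched, any-peak background and base order settings were chosen after seeing the data. Taking the strongest pooled peaks in place of the IDR list gave the identical 5033 peaks, so that setting tests nothing. Replicate agreement has no value with a replicate left out. Leaving that setting out, the promoter share kept its direction and its side of the threshold in the 6 others run. With the 1 kb window it ranged from 57.6% to 72.8%, and it was 48.6% with 500 bp and 69.3% with 2 kb. The ratio of summits to flanks for TTTATKG kept both too, from 1.28 within 200 bp to 1.82 in the 1000 strongest peaks. These settings do not remove base composition as an account of it. The ratio to matched genome sites, a different measure, was 1.16, and 4 of 50 other orders were as high there. Replicate agreement moved from 70.1% to 76.4% with 1 bp of overlap, 56.55% with a larger reciprocal overlap of the intervals, 58.2% within 50 bp, 76.1% within 250 bp, 75.8% with the 2516 strongest peaks of each and 57.7% with double the number. The count of lists above the background, 4, was 1 in the 1000 strongest peaks and 2 with a 5 kb window, a 500 bp window, the most upstream TSS, GC matched lists or the any-peak background, and without a replicate it ranged from 2 to 4. Where it did not pass, the EGFR list (66.7%) stood at 16.7% in the 1000 strongest peaks, 33.3% in the 2516 strongest and with a 500 bp window, 75% with a 5 kb window, 58.3% at the most upstream TSS, 72.7% against the any-peak background and 66.7% against GC matched lists and without replicate 2. Without replicate 1 it passed, also at 66.7%. The Polycomb list (54.5%), where it did not pass, stood at 72.7% with a 5 kb window, 80% against the any-peak background, 50% with a 500 bp window and at the most upstream TSS, and 54.5% against lists matched on GC content or gene territory. Without replicate 2 it stood at 50% and did not pass, and without replicate 1 at 54.5% and passed. Cytoplasmic ribosomal protein genes stood at 10.9% and mitochondrial ones at 17.8% in the 1000 strongest peaks, and neither passed. Fewer peaks were tested there, but the Polycomb list still passed, at 31.8%, and whether the ribosomal enrichment itself shrank was not tested. Complexes passing rose from 0 to 1, the bithorax complex, with 10 kb added (44 summits) and with intervals centred on genes (42 summits). The 5' UTR ratio of 0.536 was 0.385 in the 1000 strongest peaks, where fewer peaks were tested, and 0.692 against GC matched bases, and neither passed. The other exon ratio of 0.921, not past the threshold, ranged from 0.970 to 1.09 without a replicate, and was 0.488 in the 1000 strongest peaks and 0.776 in the 2516 strongest. The coding ratio of 0.00724 was 0 in the 1000 strongest and 0.00290 in the 2516 strongest. In the 1000 strongest the 3' UTR ratio of 0.1435 was 0.0677 and the intergenic ratio of 0.553 was 0.345, and against GC matched bases the 3' UTR ratio was 0.0884, all still past the threshold. The distal odds ratio of 1.19 was 0.908 in the 1000 strongest peaks, 1.08 in the 2516 strongest and 1.13 to 1.40 without a replicate, and other base orders had a median of 0.922, with 4 of 50 as high as the motif. The rank correlation of -0.0293 was -0.0433 in the 1000 strongest peaks, 0.0107 in the 2516 strongest, 0.00297 within 50 bp and -0.0241 to -0.00604 without a replicate, against a median of 0.0183 for other orders, of which none of 50 was as low (lowest -0.0130). Within 200 bp, the GAGA ratio turned to 1.02 and the TGATTAAT ratio to 0.895. The cause of these changes was not tested except as stated. Of 58 named genes with a promoter summit, 52 had one without replicate 1, 55 without replicate 2 and 47 among the 2516 strongest. With a 500 bp window 47 had one, as did 47 at the most upstream TSS, where Abd-B had none. Lost without replicate 1 were Csp, Ir60b, RpL41, Scr, nub and rtv, and without replicate 2 Gr32a, btd and loco. The summits of Scr, RpL41, nub and bowl had no replicate 2 partner, and those of btd and Gr32a no replicate 1 partner. Unknown depth limits all comparisons of weak peaks.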

Other observations

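The tests of chromosome 4, the split of motifs by distance and the matched sites were chosen after the data had been seen. Chromosome 4, the small dot chromosome, held 1 IDR peak, where its length would give 50.7 (exact binomial test, two-sided, p = 9.51e-21). That peak, at 1027120 to 1027441, ranked 82 and had its summit 185 bp upstream of PlexA, which encodes a semaphorin receptor. Of the 80 protein-coding genes of this chromosome 1 had a promoter summit (1.25%, Fisher's exact test, two-sided, p = 4.95e-09), against 24.98% of all protein-coding genes. The replicate 1 list held 13 peaks there, the replicate 2 list 4 and the pooled list 3, of 30000 peaks each. The shortage thus held in the full lists too, where a low rank does not mean enrichment. A lack of binding therefore cannot be told apart from a general lack of called peaks on this chromosome. The GC content of chromosome 4 was 34.8%. On the other arms the density ran from 32.2 IDR peaks per Mb on 2R to 41.8 on X. PlexA was chosen after its value was seen.

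The DREF motif TATCGATA lay at 6.86% of promoter summits and in 0.714% of their flanks, a ratio of 9.62 (exact McNemar test, adjusted p = 5.05e-37), and none of 50 other orders was as high. At summits farther than 1 kb from a TSS it lay at 0.526% against 0.191%, a ratio of 2.75 (exact McNemar test, adjusted p = 0.169). Of its other orders 1 of 50 was as high there, and the difference between the ratios was not tested. GAGAG, below its flanks at IDR summits, was above genome sites matched on GC content and promoter class, at 20.6% against 16.9% (ratio 1.22), and none of its 9 other orders was as high. Against the same matched sites motif 1 had a ratio of 3.799 and DREF 3.27, each above all 50 of their other orders, and BEAF-32 had 1.30, with 1 of 50 as high. The Caudal motif TTTATG had a ratio of 1.13, above all of its 29 other orders, although 17 of them were as high against the flanks. TTTATG lies inside TTTATGG, a form of TTTATKG, and CGATA inside TATCGATA, so neither pair is separate evidence. The Hox core TAATTA stood at 1.05, with 8 of 13 orders as high. The ratio turned below 1 for TGATTTAT (0.923, 47 of 50 orders as high) and TGATTAAT (0.779, 50 of 50). CAGGTA stood at 0.929 (29 of 50).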
